A study of Mus musculus with 16 samples.

How the data were processed

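Chromatin accessibility was measured by ATAC-seq, which marks open DNA by transposase insertion, in mouse Rx:GFP knock-in embryonic stem cells (ESCs) and in embryoid bodies made from them. Per the labels, transposition ran at 37C for 30 min, and embryoid bodies grew by the SFEBq method in GMEM with 5% KSR and received 2% matrigel on day 1. The data analysed here are 16 peak lists, 12 from ESCs and 4 from embryoid bodies. Per the labels, Bowtie2 2.3.5, SAMtools, Genrich 0.6, MACS2 2.1.2 and DESeq2 were used with genome build mm10, without the role of each tool.

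Each deposited ESC list gives for every peak a score within the list, a signal of unstated scaling that is never under 200, a −log10 p against the background of that library, and a summit. The q column of the ESC lists is -1 throughout, and the caller of these lists is not stated. Each deposited embryoid body list gives a score, a ratio (fold enrichment of the peak over local background) and −log10 p and −log10 q values, and has no summit. Peak names in the embryoid body lists have the form that MACS2 writes, and the authors removed blacklisted regions from them, as their names say. The lists hold no read counts and no library totals, so the depth is unknown and no counting interval can be given. Signals and ratios were used only to rank peaks within a list and to describe single peaks, and were never compared between ESC and embryoid body lists.

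Peaks on chromosomes 1 to 19, X and Y were kept. For each comparison, the peaks of the libraries compared were merged into regions where they overlapped by at least 1 bp. A region was counted as found in one group only when every library of that group and no library of the other had a peak in it. These counts have no test of their own. With 4 libraries against 2, a region must be in 4 lists for one direction and in 2 for the other. The counts of the 2 directions then do not compare directly. All counts are given beside the same total (both directions added) for all other splits of the same libraries into groups of the same sizes. Where list lengths differ much between groups, other splits mix short and long lists, which holds their totals low by construction. This limits the comparison wherever backbone, S91K-Y191F or parental ESC lists are included. Numbers per library (log10 peak number, share of peaks near gene ends) were compared by two-sided exact permutation tests. The smallest p is 0.333 for 2 libraries against 2 and 0.0667 for 4 against 2, so these designs cannot reach 0.05. The labels do not say that replicates are separate cultures, so every p-value measures the spread between these libraries only.

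The gene table holds 21883 protein-coding genes of mm10 (GRCm38.p6) without strand. A gene end peak is therefore a peak within 1000 bp of either end of a protein-coding gene, which replaced the planned transcription start site. Regions were assigned to the protein-coding gene with the nearest end within 100 kb. The 16 gene lists (465 genes, all of which matched) cover naive and core pluripotency, formative and primed pluripotency, neuroectoderm and neural progenitor, eye field and retinal progenitor, primitive streak and mesoderm, endoderm, trophectoderm, fibroblast and mesenchyme, p53 targets, COMPASS and MLL complex subunits, ubiquitously expressed genes, Wnt, Nodal and BMP signalling, cilium and neuronal maturation, ribosomal protein genes, Hox clusters, and canonical histone genes. For each list, the difference between regions found only in the first group and only in the second was taken as a percentage of all regions assigned to the list and found in every library of at least 1 group. It was compared, two-sided, with 10000 random gene sets matched on the number of regions per gene and drawn with replacement (a permutation test over genes, which are not independent replicates). P-values were adjusted over the lists of a comparison by the Benjamini-Hochberg method, and lists with fewer than 3 genes with regions were not tested.

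Genes named in the text follow a rule: Wdr5 and Trp53 in every library; per comparison and list, up to 3 genes with the most regions found in only one group; per comparison and direction, the 5 genes with the most such regions; and per comparison and list, up to 3 genes with an end peak in every library of one group and none of the other. Groups, comparisons, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined, although file sizes were visible then. The alternatives fixed then were equal list length (the top peaks by signal, at the length of the shortest list), the upper 50% of each list by the authors' p, an overlap of at least 50% of the shorter peak, 500 bp windows around summits, merging across 200 bp, autosomes only, gene end windows of 500 and 2500 bp, assignment within 50 kb, 3 of 4 p53 knockout libraries, all but 1 library per side, replicate number as a block, and leaving out each library. Chosen after seeing the data were the removal of clustered windows, the removal of chromosome 8, assignment by gene span, the use of only the 6 ESC lists with the widest peaks, and either gene end in place of the start site. Clustered windows are the 45 windows of 1 Mb that hold 5 or more peaks of the shortest ESC list, which has 1535 peaks. That list is backbone replicate 1, so the choice of windows favours high counts there in that list and in lists like it.

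A comparison of 8 ESC libraries with wild-type WDR5 against 4 without was made because, of the planned comparisons between groups, only it can reach a p under 0.05, with a smallest p of 0.00202 over 495 arrangements. Similarity between ESC lists was the Jaccard index of the top 1535 peaks, tested with 100000 relabelings. The region sets and the gene list test were tried on simulated presence and absence made from the embryoid body comparison with 149618 regions. Unequal list lengths, ranking at equal length and list similarity were not simulated. Planted were 200 regions, each with a 95% chance in every library of its group. Of these, 180 were drawn as present in all libraries of that group and in none of the other. All 180 were recovered and 0 were called in the opposite direction, which follows by construction because the simulated regions never overlap. Without planted regions, 4652 and 4647 regions fell into the 2 sets, and 5 of 200 random gene lists had an unadjusted p under 0.05. A planted list of 25 genes gave a permutation p of 1e-04, the smallest that the random sets can give. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used. Motif analysis was left out for want of a genome sequence.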

Results

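Open chromatin was profiled by ATAC-seq in mouse Rx:GFP knock-in ESCs maintained in 2i+LIF, and in SFEBq embryoid bodies, a culture that leads to neural and retinal tissue. Rx (Rax) is a transcription factor of the eye field, WDR5 is a scaffold subunit of the COMPASS and MLL histone methyltransferases, and p53 (gene Trp53) is a stress-induced transcription factor. The 16 libraries form 8 groups of 2 replicates. The ESC groups are the parental line, the p53 knockout clones C9 and H9, and Wdr5 and p53 double knockouts carrying the backbone plasmid, wild-type WDR5 (WDR5WT) or S91K-Y191F WDR5. The embryoid body groups are parental, at day 4 by label, and double knockout, whose labels give no day.

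Peak numbers differed widely between the ESC groups and little between the embryoid body groups. Backbone ESCs had 2013.5 ± 677 peaks, S91K-Y191F ESCs 10716 ± 7837, parental ESCs 14849 ± 13461, clone C9 29044 ± 3873, clone H9 30955 ± 247 and WDR5WT ESCs 31244 ± 2072 (SD, n = 2 each). Parental embryoid bodies had 83055 ± 10439 peaks and double knockout embryoid bodies 85876 ± 10988 (SD, n = 2 each). Replicates were far apart in parental ESCs (24367 and 5330 peaks) and in S91K-Y191F ESCs (5174 and 16257 peaks). The number of peaks reflects depth and calling as well as chromatin, and the depth is unknown.

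**Figure D1:**
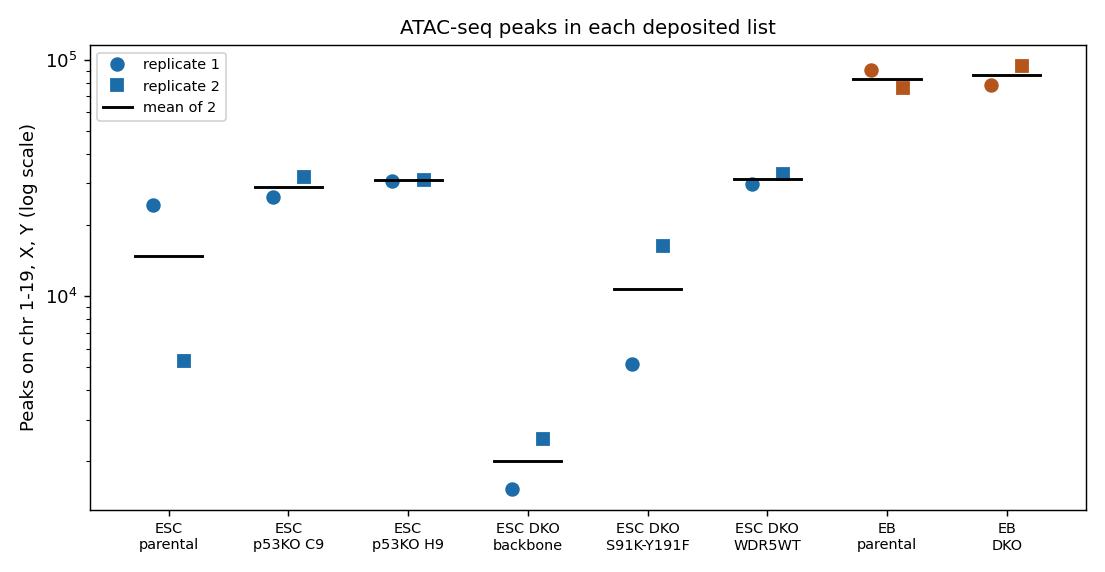
Peaks on chromosomes 1 to 19, X and Y in each list (log scale), by group; circles are replicate 1, squares replicate 2 and lines the mean of 2. Backbone ESC lists hold 1535 and 2492 peaks, and embryoid body lists 75673 to 93646.

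The 12 ESC lists fell into 2 sets of 6 that followed neither Wdr5 nor p53 status alone. In parental, backbone and S91K-Y191F lists the widest peak spanned 34576 to 45753 bp, and 1049 to 1443 peaks lay in the 45 clustered windows, among them a window of chromosome 8 that holds Gm15319 and Gm21119. In C9, H9 and WDR5WT lists the widest peak spanned 7727 to 15921 bp and 733 to 846 peaks lay in those windows. These are called the wide-peak and the narrow-peak lists here, after their widest peak only. Over all sequences in the lists, median peak width was 579 to 657 bp in the wide-peak and 621 to 668 bp in the narrow-peak lists. Peaks of the narrow-peak lists were thus not narrower in general. The clustered windows come from backbone replicate 1, which favours higher counts in lists like it. The narrow-peak lists are those of all ESCs that lack p53 and have wild-type WDR5, so list set coincides with this combined genotype. The labels name no batch. Comparisons within 1 set come first below; in comparisons across the sets, set and genotype cannot be separated.

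In embryoid bodies, most regions found in both libraries of a genotype were found in all 4 libraries, although only 42539 of all 149618 merged regions were. The regions that differed included some at developmental regulators, which the naming rule picks from mostly developmental gene lists. Six3, an eye field and forebrain regulator, had an end peak in both parental and neither double knockout library, and a parental-only region at chromosome 17, 85628596 to 85629085, with a fold enrichment over local background of 2.76 to 3.37. End peaks in both parental libraries alone were also found at Esrrb, a naive pluripotency factor (chromosome 12, 86360802 to 86361275), Tfap2a, a factor of trophectoderm and surface ectoderm, and the positional regulators Hoxa4 and Hoxb13. Regions found only in parental embryoid bodies lay near Tcf7l1 (5 regions) and Tcf7l2 (4), which mediate transcription in response to Wnt, near Dkk1 (3), a secreted Wnt antagonist, and near Wnt3 (3), a ligand of primitive streak formation. The same held for Dnmt3a (4), a DNA methyltransferase, Olig2 (3), a neural progenitor factor, Meis1 (3), a homeodomain factor of the eye field, Map2 (3), a neuronal cytoskeletal protein, Cxcr4 (3), a chemokine receptor, Fgfr2 (3), an FGF receptor, and Kdr (3), a VEGF receptor. Regions found only in double knockout embryoid bodies lay near Spock3 (8), Unc5d (7), Tll1 (5), Tusc3 (5), Kcnc2 (5), and Zfp42 (3; also known as Rex1, a naive pluripotency marker), and ends of Apoe and Rpl39l had a peak only there.

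In counts, 42539 regions were found in all 4 embryoid body libraries, 7024 in both double knockout and neither parental library, and 6389 in the reverse pattern. The sum of the last pair, 13413, compares with at most 6163 for the other 2 of the 3 splits. Simulated lists with presence drawn without regard to genotype gave 4652 double-knockout-only and 4647 parental-only regions. These are counts per direction, to be set beside 7024 and 6389. The simulation drew libraries independently and with the same chance in each, so it leaves out list length and likeness of replicates. Counts depended on single libraries: regions found only in the double knockout numbered 29113 without double knockout replicate 1, 20636 without double knockout replicate 2 and 12822 without parental replicate 1, and those found only in parental embryoid bodies 12317 without double knockout replicate 2, 18586 without parental replicate 1 and 26031 without parental replicate 2. An end peak was present in all 4 libraries at 13394 genes, only in the double knockout at 152 and only in parental embryoid bodies at 179. Gene end peaks made up 17.7% ± 1.80 of double knockout and 18.7% ± 1.72 of parental peaks (SD, n = 2 each; two-sided exact permutation p = 0.667). Since the day of the double knockout embryoid bodies is not labelled, a difference in day is not excluded.

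None of the 16 gene lists differed from random gene sets after adjustment (0 lists; 1 list at an unadjusted p under 0.05). That list was Wnt, Nodal and BMP signalling, with 9 double-knockout-only and 28 parental-only regions of 198 (a difference of -9.60% where random sets had a median of -2.53%; permutation p over random gene sets = 0.0415, adjusted p = 0.535), where 12 of 30 genes had more parental-only regions and 2 more double-knockout-only regions. Parental-only regions also outnumbered the others near formative and primed pluripotency genes (16 against 4), eye field and retinal progenitor genes (16 against 4), neuroectoderm genes (18 against 8), ribosomal protein genes (18 against 8) and Hox genes (6 against 1). Random sets for these lists also had a parental excess, with medians of -2.78%, -2.68%, -2.29%, -1.10% and -1.59% where the lists had -8.57%, -8.11%, -5.65%, -5.59% and -7.94% (permutation p = 0.167, 0.167, 0.386, 0.137 and 0.267). The reverse count was seen near p53 targets (7 double-knockout-only, such as those at Plk2 and Rrm2b, against 2; permutation p = 0.150, adjusted p = 0.535). Naive pluripotency genes (12 against 14), primitive streak genes (11 against 13), endoderm genes (8 against 9), trophectoderm genes (5 against 7), fibroblast genes (4 against 6), COMPASS subunits (1 against 3), ubiquitously expressed genes (2 against 6), cilium and neuronal maturation genes (6 against 7) and histone genes (2 against 2) are given in the same order, double knockout first. Without double knockout replicate 1, which leaves 1 double knockout library and so no measure of spread between replicates, 3 lists passed adjustment, with fewer double-knockout-only regions than random sets: Wnt, Nodal and BMP signalling (adjusted p = 0.0080; range over its alternatives 0.0080 to 0.779), eye field (0.048; 0.048 to 0.95) and ribosomal protein genes (0.048; 0.048 to 0.95). Leaving out any 1 of the other 3 libraries gave 0 lists.

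**Figure D2:**
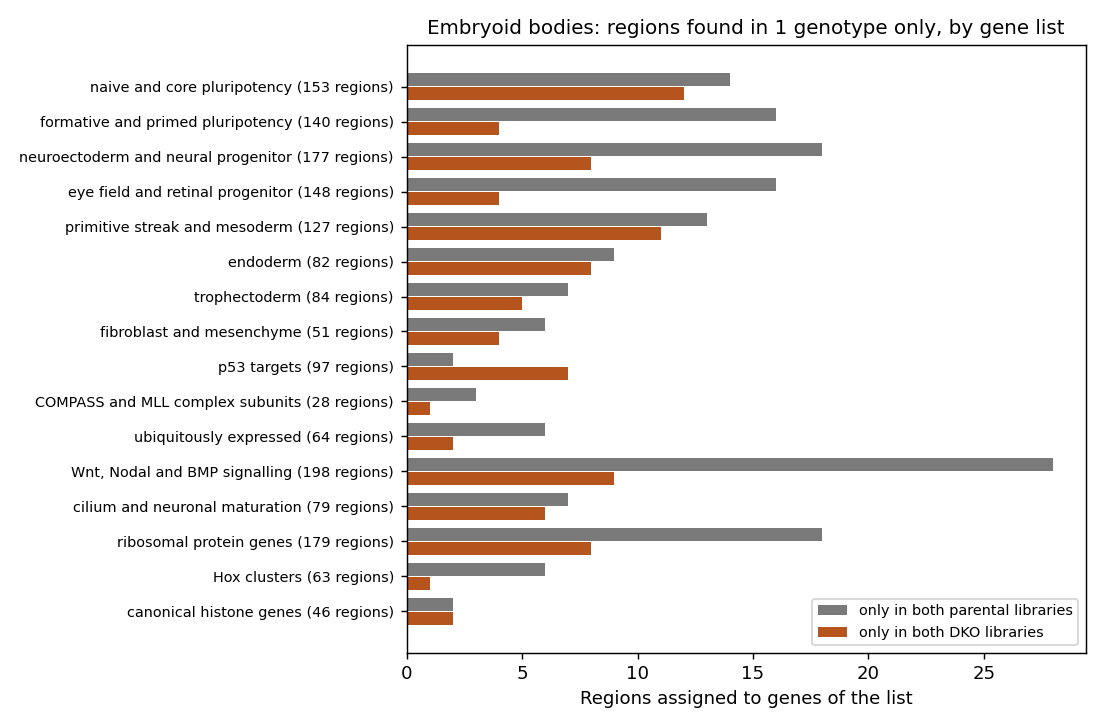
Regions assigned to each gene list that were found only in both parental (grey) or only in both double knockout (orange) embryoid body libraries; the regions tested per list are in parentheses. Wnt, Nodal and BMP signalling has the largest parental excess, 28 against 9, and no list passes adjustment.

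Spock3, Unc5d, Tll1, Tusc3 and Zfp42 lie on chromosome 8, as did 930 of 7024 double-knockout-only regions (13.2%) against 201 of 6389 parental-only regions (3.15%) and 5.90% of shared regions. Outside clustered windows, chromosome 8 held 7.05% and 7.08% of peaks in double knockout and 4.89% and 4.93% in parental embryoid bodies. The same was seen in ESCs, where the 10 libraries without p53 had 7.64% to 13.4% and the parental libraries 4.75% and 5.26% (two-sided exact permutation p = 0.0303, smallest possible 0.0152, n = 10 and 2). Within the wide-peak lists the 4 libraries without p53 had 7.64% to 13.4%; the narrow-peak lists include no parental library and had 7.87% to 8.90%. Leaving out chromosome 8, 6094 double-knockout-only and 6188 parental-only embryoid body regions remained. This share was examined because it stood out in the data, and the p is not corrected for choosing among 21 chromosomes. The permutation test in ESCs treats the 12 libraries as independent, although they are 6 pairs of replicates. Arrangements that keep pairs together cannot give a p under 0.05. Outside clustered windows, chromosome 6 had a lower share in all 10 ESC libraries without p53 than in parental ones (means 5.61% and 6.99%). In embryoid bodies its means were 5.53% and 5.47%.

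**Figure D3:**
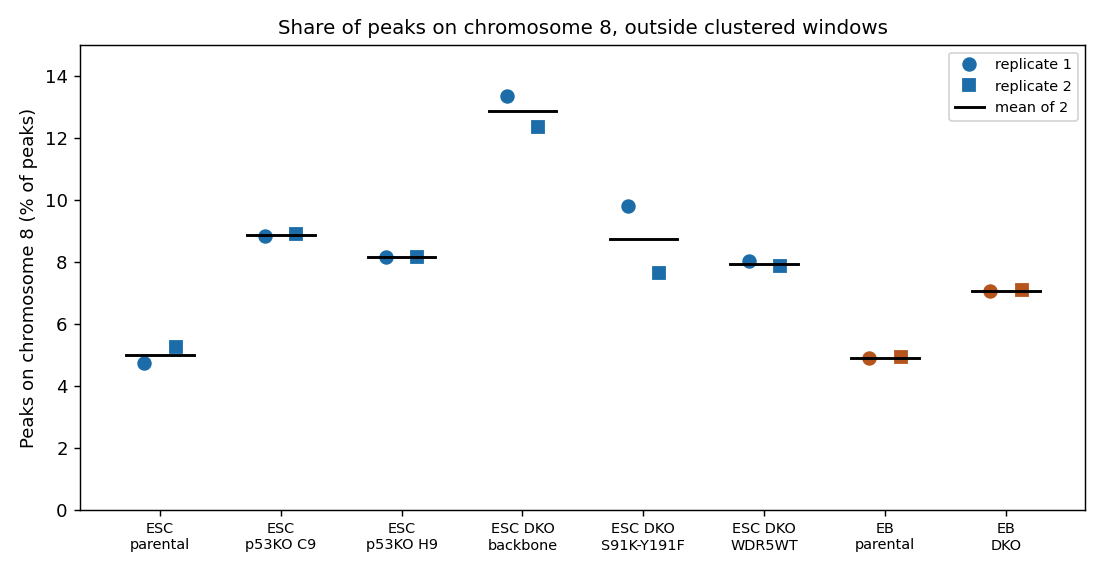
Percent of peaks outside clustered windows that lie on chromosome 8, by group; circles are replicate 1, squares replicate 2 and lines the mean of 2. Parental libraries sit between 4.75% and 5.26% and all libraries without p53 between 7.05% and 13.4%.

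Backbone ESCs, which lack WDR5 and p53, were compared with parental ESCs for the effect of both losses in undifferentiated cells, within the wide-peak lists. Peaks at ends of Nanog (chromosome 6, 122707094 to 122707661), Stat3 (chromosome 11, 100939274 to 100939958) and Tbx3 (chromosome 5, 119670328 to 119671096), all parts of the naive pluripotency network, were present in both parental lists and absent from both backbone lists. The same pattern was found at the neural factors Zic2, Zic5 and Sox21, at the p53 targets Apaf1, a core of the apoptosome, Ccng1 (2 regions) and Polk, a DNA polymerase of lesion bypass, and at Psip1, a chromatin reader that binds MLL. Parental-only regions also lay near Tet2 (3), a DNA demethylase, H2az1 (3), a variant histone gene, Stmn2 (2) and Syt1 (2), neuronal genes, and the ubiquitously expressed Eef2 and Ppia. Backbone-only regions lay mostly near Gm15319 (8) and Gm21119 (7), and 87.9% of all backbone-only regions fell in clustered windows. Those windows were chosen from backbone replicate 1, 68.3% of whose peaks lie in them, so a high share was favoured by construction.

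Parental-only regions numbered 2886, backbone-only regions 107 and shared regions 872. The sum of the first 2 counts, 2993, compares with at most 207 in the other 2 splits, which mix short and long lists. An end peak was present only in parental lists at 1734 genes and only in backbone lists at 4, so the genes named above are among many. Log10 peak number was 3.29 ± 0.149 against 4.06 ± 0.467 (SD, n = 2 each; exact permutation p = 0.333, the smallest possible). At equal list length, 334 backbone-only and 332 parental-only regions were left. Parental-only regions numbered 22190 without parental replicate 2, and backbone-only regions 218 without backbone replicate 1, 224 without backbone replicate 2 and 300 without parental replicate 2. No gene list of 12 tested differed from random sets (0 at an unadjusted p under 0.05); examples are naive pluripotency genes (0 backbone-only and 11 parental-only of 17) and ribosomal protein genes (0 and 12 of 15).

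S91K-Y191F WDR5 was compared with the backbone for what the mutant protein restores, again within the wide-peak lists. Mutant lists had end peaks that both backbone lists lacked at Tbx3 (chromosome 5, 119670266 to 119671103), Stat3 (chromosome 11, 100939274 to 100939922), Zic2, Zic5, and the Wnt effector Tcf7l1 (chromosome 6, 72788922 to 72789739). They also had them at the methyltransferase genes Kmt2b (chromosome 7, 30588704 to 30589702) and Kmt2c, at Psip1, at the eye field genes Fzd5 and Mitf, a Wnt receptor and the pigment cell regulator, and at Meis2. Among p53 targets, Apaf1, Polk and Sesn1 had such peaks, as did the mesenchymal filament gene Vim. The genes with the most mutant-only regions were Shf (4), H2az1 (3), Hmox1 (3, haem oxygenase), Hmgxb4 (3) and Rbpj (3, the Notch effector). Gas8 had the most backbone-only regions (6). Of all backbone-only regions, 77.9% fell in clustered windows. Those windows were chosen from backbone replicate 1, so a high share was favoured by construction.

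Mutant-only regions numbered 2603 and backbone-only regions 68. Their sum of 2671 compares with at most 182 in the other 2 splits, which mix short and long lists. At equal list length the counts were 274 and 261. Mutant-only regions numbered 13941 without S91K-Y191F replicate 1, and backbone-only regions 180 and 108 without S91K-Y191F replicates 1 and 2 and 157 and 166 without backbone replicates 1 and 2. An end peak was present only in mutant lists at 1820 genes and only in backbone lists at 0. Of 10 gene lists tested, 0 passed adjustment and 0 had an unadjusted p under 0.05; naive pluripotency genes had the smallest p, with 3 mutant-only regions of 9 (permutation p = 0.0900, adjusted p = 0.753).

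WDR5WT ESCs were compared with p53 knockout ESCs, which keep their own Wdr5, within the narrow-peak lists. Most regions found in every library of 1 group were shared with the other, although only 17458 of all 46925 merged regions were found in every library. Both WDR5WT lists and no p53 knockout list had end peaks at Lin28a (chromosome 4, 134018184 to 134019223), an RNA-binding pluripotency factor, at Lefty1 (chromosome 1, 180934388 to 180935118), a Nodal inhibitor, and at Sp5 (chromosome 2, 70476070 to 70477182), a direct Wnt target. The same was found at Mesp1 (chromosome 7, 79792579 to 79793564), a mesoderm regulator, at Nes (chromosome 3, 87970913 to 87971923), a neural progenitor filament, at Tbx2, an eye field factor, at the laminin gene Lamb1, at Hoxc6 and at the histone gene H2bc21. WDR5WT-only regions also lay near Tmem117 (4), Clmp (3) and Gli2 (3; a Hedgehog effector). Regions found in all 4 p53 knockout libraries alone lay near Bach1 (3), Lonrf1 (3), Pgm2 (3), Rab38 (3) and Slc24a5 (3), and 1 each near the naive pluripotency genes Tfcp2l1 and Nr5a2.

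In all, 17458 regions were shared, 1527 were WDR5WT-only and 867 were p53-knockout-only. The sum of the last 2 counts, 2394, compares with at most 1361 in the other 14 of 15 splits. An end peak was present only in WDR5WT lists at 250 genes and only in p53 knockout lists at 26. The former requires a peak in 2 of 2 lists and the latter in 4 of 4, so these counts do not compare directly. WDR5WT-only regions numbered 4321 and 2992 without WDR5WT replicates 1 and 2. Those found only in p53 knockout lists numbered 1350 and 1637 without WDR5WT replicates 1 and 2, and 1400 without C9 replicate 1. When 3 of 4 p53 knockout libraries sufficed they numbered 2167, more than the 1527 WDR5WT-only regions. Peak numbers did not differ detectably (log10 4.49 ± 0.0288, n = 2, against 4.48 ± 0.0377, n = 4; SD, exact permutation p = 0.733, smallest possible 0.0667). Of 16 gene lists, 0 passed adjustment and 0 had an unadjusted p under 0.05; naive pluripotency genes had the smallest p, with 1 WDR5WT-only and 5 p53-knockout-only regions of 70 (permutation p = 0.0812, adjusted p = 0.583).

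Clones C9 and H9 share a genotype by label, so their difference gives the spread between p53 knockout clones. Both H9 lists and neither C9 list had end peaks at Dppa5a (chromosome 9, 78367820 to 78368350), a pluripotency-associated gene, at Men1 (chromosome 19, 6334722 to 6335162), the menin subunit of MLL complexes, at the Wnt coreceptor Lrp6, the FGF receptor Fgfr2, the eye field gene Six6, the midbrain gene En2, the p53 target Zmat3, the ribosomal protein genes Rps24 and Rps28, the linker histone gene H1f4 and Hoxd1. H9-only regions were also frequent near Meis2 (3). C9-only regions lay near Kcna4 (3), the imprinted gene Rtl1 (3), Zfp42 (2), Syt1 (2) and Nodal (1). Shared regions numbered 19619, C9-only regions 939 and H9-only regions 1925. The sum of the last 2 counts, 2864, compares with at most 1752 in the other 2 splits. An end peak was present only in H9 lists at 503 genes and only in C9 lists at 53. Leaving out C9 replicate 1, C9 replicate 2, H9 replicate 1 or H9 replicate 2 gave 4684, 2156, 1913 and 1919 C9-only and 3008, 4493, 4831 and 4442 H9-only regions. Of 16 gene lists, 0 passed adjustment and 1 had an unadjusted p under 0.05, fibroblast and mesenchyme genes, with 0 C9-only and 4 H9-only regions of 15 (permutation p = 0.0420, adjusted p = 0.520).

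The remaining comparisons cross the 2 sets of lists. For the loss of p53 alone, all 4 p53 knockout lists and neither parental list had end peaks at the p53 target Phlda3 (chromosome 1, 135765683 to 135766791), at the developmental regulators Hand2, Irx3 (chromosome 8, 91800896 to 91802344), Snai1, Hes5, Vax1 and Sox4, at the secreted signals or receptors Bmp7, Nog, Sfrp1 and Fzd10, and at the methyltransferase and demethylase genes Kmt2c and Kdm6a. Zfp42 (5) and Map2 (4) had several p53-knockout-only regions, and Prl2c3 (8), Isx (7), Ccser2 (6), Cdh5 (6) and Zfp352 (6) the most. Hand2, Irx3, Sfrp1, Zfp42, Isx and Cdh5 lie on chromosome 8. It held 876 of 5620 p53-knockout-only regions (15.6%), 180 of 1152 parental-only regions (15.6%) and 7.86% of shared regions. These sets thus show no chromosome 8 excess of the knockout over the parental direction. Parental-only regions lay near Gm15319 (37), Atg7 (25), Hrh1 (24), Gm21119 (22) and Gm52481 (21), and 45.1% of them fell in clustered windows. Histone genes were the only list to pass adjustment of 15 tested, with 0 p53-knockout-only and 5 parental-only regions of 22 (permutation p = 0.0005, adjusted p = 0.0075; 1 list at an unadjusted p under 0.05). H3c10, H3c14 and H3c15 are examples, members of families of near-identical genes, in which placement of reads is uncertain. Histone genes also passed in S91K-Y191F against WDR5WT and in parental embryoid bodies against parental ESCs, each time towards the wide-peak lists. They passed in no comparison within a set of ESC lists. Backbone against p53 knockout or WDR5WT lists gave no call either (permutation p = 0.308 and 0.353). Genotype and list set thus cannot be separated for this list. At equal list length 2 lists passed: histone genes (0 and 6 of 7, permutation p = 0.0004, adjusted p = 0.0052; range over alternatives 0.0045 to 0.0075) and eye field genes (6 and 0 of 10, permutation p = 0.0065, adjusted p = 0.0422; range over alternatives 0.0422 to 1).

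The counts for p53 knockout against parental ESCs were 5620 and 1152 with 3372 shared, a sum of 6772 against at most 1448 in the other 14 of 15 splits. At equal list length they were 918 and 1019; p53-knockout-only regions numbered 16220 without parental replicate 1 and 9441 when 3 of 4 p53 knockout libraries sufficed, and parental-only regions 5483 without parental replicate 2 and 632 without clustered windows. Log10 peak number was 4.48 ± 0.0377 against 4.06 ± 0.467 (SD, n = 4 and 2, exact permutation p = 0.0667, the smallest possible). An end peak was present only in p53 knockout lists at 986 genes and only in parental lists at 78.

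Backbone ESCs were set against p53 knockout and WDR5WT ESCs for the effect of WDR5 on a p53-null background, and here the short backbone lists dominated. Peaks at ends of Klf4 (chromosome 4, 55532214 to 55533657) and Nanog (chromosome 6, 122706896 to 122708052), naive pluripotency factors, Foxa2, an endoderm factor (chromosome 2, 148043673 to 148047061), and Hand2, a mesoderm factor, were present in all 4 p53 knockout lists and absent from both backbone lists. Regions found only in p53 knockout lists were most frequent near Prl2c3 (13), Chd9, Kif16b, Plcb4 and Spry2 (10 each), and included Meis2 (7), Klf4, Tfcp2l1, Zfp42 and Pax6 (6 each) and Meis1 (5). Against WDR5WT lists, such regions lay near Chd9 (16), Mef2c (14), Sall1 (12), Tns3 and Spry2 (11 each), Zfp42, Pax6 and Foxa2 (8 each), Elavl4 and Hand2 (7 each) and Tet2 (6), and ends of Lin28a, Fgf4, Eomes (chromosome 9, 118478094 to 118479858), Cdx2 and the p53 target Bbc3 had a peak in both WDR5WT lists and neither backbone list. Backbone-only regions lay near Gm15319 (47 against p53 knockout, 48 against WDR5WT), Gm21119 (37 and 36) and Hrh1 (28 in both).

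Against p53 knockout, backbone-only regions numbered 810 (77.3% in clustered windows, which were chosen from backbone replicate 1) and p53-knockout-only regions 18301. Their sum of 19111 compares with at most 1918 in the other 14 of 15 splits. Without clustered windows 184 backbone-only regions remained, and equal list length left 674 p53-knockout-only regions. Against WDR5WT, the counts were 818 backbone-only (187 without clustered windows) and 24182 WDR5WT-only (823 at equal list length). Their sum of 25000 compares with at most 9 in the other 2 splits. In both comparisons the short backbone lists hold the totals of the other splits low by construction. End peaks absent from both backbone lists were found in all p53 knockout lists at 7453 genes and in both WDR5WT lists at 9555. The reverse held at 50 and 48 genes, so the genes named above are among many. In neither comparison did a gene list pass adjustment (0 of 15 and 0 of 16; 0 and 0 at an unadjusted p under 0.05). For p53 targets, 21 of 25 and 32 of 36 regions were absent from backbone lists; for Wnt, Nodal and BMP signalling 23 of 24 and 41 of 42; for ribosomal protein genes 55 of 58 and 78 of 81.

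S91K-Y191F against WDR5WT ESCs asks what the substitutions alter, across the sets. Both WDR5WT lists and neither mutant list had end peaks at Klf4 (chromosome 4, 55532102 to 55533586), Lin28a and Fgf4, pluripotency genes, at Pax6 (chromosome 2, 105668267 to 105668996), a neural and eye factor, at Eomes, Hand2 and Foxc1, mesoderm factors, at Gata6 and Hhex, endoderm factors, at the Wnt mediator Ctnnb1 (chromosome 9, 120932956 to 120933786), at Bmp2 and Kmt2d, and at the p53 targets Bbc3, Btg2 and Eda2r. WDR5WT-only regions were most numerous near Celf4, Chd9, Mef2c and Rapgef5 (9 each), Cntnap4 (8), Foxa2 (6), and Axin2, Dnmt3a, Lef1, Sox4, Ncam1, Isl1 and Zfp42 (4 each). Mutant-only regions lay near Gm15319 (55), and ends of H2ac19, H2ac23 and H2ac24 had peaks only in mutant lists. Histone genes passed adjustment among 16 lists (4 mutant-only and 3 WDR5WT-only regions of 34, a difference of 2.94% where random sets had a median of -38.2%; permutation p = 1e-04, the smallest possible, adjusted p = 0.0016), with the same limit on near-identical copies. Another 4 lists had an unadjusted p under 0.05. Primitive streak and mesoderm (0 mutant-only and 25 WDR5WT-only of 33, adjusted p = 0.132) and Wnt, Nodal and BMP signalling (0 and 29 of 42, adjusted p = 0.132) had more WDR5WT-only regions than random sets. COMPASS and MLL subunits (0 and 2 of 19, permutation p = 0.0160, adjusted p = 0.128) and ubiquitously expressed genes (0 and 6 of 29, permutation p = 0.0275, adjusted p = 0.132) had fewer.

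Mutant-only regions numbered 966 (61.7% in clustered windows, 370 without those windows), WDR5WT-only regions 13557 and shared regions 3555. The sum of the first 2 counts, 14523, compares with at most 470 in the other 2 splits, which mix short and long lists. Equal list length left 1318 WDR5WT-only regions and brought 3 lists past adjustment: histone genes, ribosomal protein genes and neuroectoderm genes. Mutant-only regions numbered 3099 without S91K-Y191F replicate 1, and WDR5WT-only regions 21917 without S91K-Y191F replicate 2. An end peak was present only in WDR5WT lists at 3473 genes and only in mutant lists at 80.

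Of 2880 regions found in both parental and neither backbone list, 79.4% were found in both WDR5WT lists, 78.4% in both C9 lists, 79.3% in both H9 lists and 46.9% in both S91K-Y191F lists. The mutant replicates differed, with 47.3% in replicate 1 and 94.5% in replicate 2. Of 856 regions kept in parental and backbone lists, 41.2%, 40.1%, 40.5% and 94.4% were found in these groups, in the same order; outside clustered windows, of 376 such regions, the shares were 60.6%, 59.8%, 60.9% and 96.5%.

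Libraries without wild-type WDR5 (backbone and S91K-Y191F, n = 4) were compared with those that have it (n = 8). All 8 and none of the 4 had a peak at the ends of Dicer1 (chromosome 12, 104751641 to 104752675), which encodes the microRNA-processing enzyme, Cdon (chromosome 9, 35420835 to 35422542), a Hedgehog coreceptor, Actr3b, Cpq and Dab1, an adaptor of Reelin signalling, and near Dppa3, a marker of naive cells and germ cells. Stmn2 had 1 region of this kind. Log10 peak number was 3.63 ± 0.446 without and 4.38 ± 0.266 with wild-type WDR5 (SD; two-sided exact permutation p = 0.00404, adjusted over 3 measures p = 0.0121), with 3 of 4 libraries below all 8. Among the top peaks at equal list length, gene end peaks made up 39.2% ± 17.5 against 67.3% ± 14.0 (SD; exact permutation p = 0.0141, adjusted p = 0.0212; 2 of 4 libraries below all 8), and in whole lists 36.1% ± 12.9 against 34.5% ± 4.35 (exact permutation p = 0.778). Within the wide-peak lists alone (4 against 2) the differences were -0.430 in log10 peak number (p = 0.333) and -6.47 percentage points among top peaks (p = 0.667, exact permutation tests); with a smallest possible p of 0.0667, neither could pass the threshold there. Without clustered windows the top-peak difference was -20.1 (p = 0.0505) and the whole-list difference 11.6 (p = 0.0263, exact permutation tests). These tests treat the 12 libraries as independent, although they are 6 pairs of replicates, and the 15 arrangements that keep pairs together cannot give a p under 0.05. Without backbone replicate 1 the top-peak difference was -20.9 (p = 0.0545) and the whole-list difference 7.62 (p = 0.0303); the whole-list difference was -2.34 and -0.249 without S91K-Y191F replicates 1 and 2 (exact permutation tests).

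Regions in all 8 and none of the 4 numbered 58. Regions in all 4 and none of the 8 numbered 25, of which 88% fell in clustered windows and 80% on chromosome 8. Each of the 25 has a peak in backbone replicate 1, from which the windows were chosen. Of its peaks, 68.3% lie in the windows, so a high share was favoured by construction. None of 11 gene lists passed adjustment (0; 0 at an unadjusted p under 0.05). Replicates resembled each other more than other libraries did, with a mean Jaccard index of 0.588 within groups and 0.328 between groups (permutation p = 0.00019); between groups it was 0.481 within a set of lists and 0.226 across the sets.

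Parental embryoid bodies were compared with parental ESCs for differentiation; file format differed along with the cells, and the caller of the ESC lists is not stated. Regions found only in embryoid bodies lay near Meis1 (14), Meis2 (13), Lhx2 (8; an eye field factor), En2 (9), Irx3 (10), Foxd3 (10), Bmp4 (8), Dnmt3b (9) and Dnmt3a (12), and near Esrrb (13), Tcf7l1 (12) and Fgfr2 (12). Bcor (20), Igsf21 (20) and Casz1 (19) had the most. Hox genes had 45 embryoid-body-only and 0 ESC-only regions of 51 (permutation p = 0.0037, adjusted p = 0.0296), including Hoxb1 (6; chromosome 11, 96365540 to 96366031) and Hoxa13 (3; chromosome 6, 52260739 to 52261101), and an excess over random sets in embryoid bodies. Histone genes had 13 and 4 of 46, fewer embryoid-body-only regions than random sets (permutation p = 0.0004, adjusted p = 0.0064). Only ESC lists had an end peak at the elongation factor gene Eef2 (chromosome 10, 81182404 to 81183164), and 39.7% of ESC-only regions fell in clustered windows, as near Gm15319 (47).

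Embryoid-body-only regions numbered 42523, ESC-only regions 1653 and shared regions 3006. The sum of the first 2 counts, 44176, compares with at most 840 in the other 2 splits, which mix short and long lists. Embryoid-body-only regions numbered 74969 without parental embryoid body replicate 2, and ESC-only regions 8171 without parental ESC replicate 2 and 996 without clustered windows. At equal list length 2509 and 2244 were left and neither call held: histone genes had an adjusted p of 0.052 (range over alternatives 0.0016 to 0.052), and Hox genes were too few to test. Of 16 lists, 2 passed adjustment and 6 had an unadjusted p under 0.05. At 5442 genes an end peak was present only in embryoid body lists, and at 131 only in ESC lists. Eef2 and the other genes named above are thus among many.

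A peak at an end of Wdr5 (chromosome 2, 27515147 to 27536535) was found in WDR5WT replicate 2 and in all 4 embryoid body lists. For Trp53 (chromosome 11, 69580348 to 69591873) it was found in parental replicate 1, both H9 lists, S91K-Y191F replicate 2, WDR5WT replicate 2 and all 4 embryoid body lists. A peak at a gene end does not test a knockout, whose lesion the labels do not describe.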

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

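The tests of repeat clusters on chromosome 8, of list length, of both genotype explanations and of the highest −log10 p for the clustered windows, and of depth in the backbone lists were chosen only after the result was seen; the other tests in this part were written down before their result was seen.

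Chromosome 8 held a larger share of peaks in all 10 p53-null ESC libraries and both double knockout embryoid body libraries than in any parental library, the largest such shift of 21 chromosomes in both cell types. Repeat clusters and list length do not account for it: outside clustered windows the lowest p53-null ESC library stayed 2.39 percentage points above the highest parental one, and at equal list length the embryoid body groups differed by 1.59 points without overlap. Extra copies of chromosome 8 may account for it. Double-knockout-only regions were in excess in 13 of 13 bins of 10 Mb along the chromosome, against 124 of 262 bins (47.3%) elsewhere. The excess was uneven, with 127 against 7 regions from 50000001 to 60000000 and 41 against 32 from 110000001 to 120000000. The bins divide the same excess that raised the question, so their sign does not separate extra copies from another cause that acts along the chromosome. Copy number was not measured, and a direct effect of losing p53 stays open as untested, because the labels do not say whether the p53-null lines share an ancestor.

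Peaks in clustered windows separated parental, backbone and S91K-Y191F ESC lists from the other 6. The windows were chosen from backbone replicate 1, which favours higher counts in lists like it, and the gaps below carry that limit. A loss of p53 or of WDR5 that raises the count does not account for this, since both parental lists held at least 397 more such peaks than any p53 knockout list, and list length does not, since the longest of the 6 lists held 1.71 times the highest of the others. The other 6 are all libraries that lack p53 and have wild-type WDR5, and every one lay at least 203 peaks below the rest, so loss of p53 lowering the count where WDR5 is wild type may account for it and cannot be told apart from processing that differed between the sets. The test written for processing gave a gap of -0.105: the sets overlapped in median −log10 p of their lowest-signal peaks, named beforehand as evidence against it. The narrow-peak set (3.29 to 3.36) lay wholly within the range of the other (3.17 to 3.39), but this median misses a difference in p that the sets do show, since the highest −log10 p outside clustered windows ran from 23.9 to 36.4 in the wide-peak lists and from 11.9 to 13.8 in the others, so processing stays open.

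Backbone ESC lists were the shortest of all. Lower depth or quality of these libraries could account for this, and so could the loss of WDR5; the 2 cannot be told apart. At equal list length outside clustered windows, the mean Jaccard index of backbone with parental lists was 0.295, below the lowest value between replicates (0.408), which would speak against depth alone. The 4 pairs, however, ran from 0.167 to 0.445, which overlaps the replicate values of 0.408, 0.459 and 0.462. Parental replicates, of 1 genotype, differed 4.57-fold in list length.

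In groups of 4 to 10 libraries, a library far from the others is marked by chance in about 1 of 20 groups, and 15 such checks were made. Clone C9 replicate 1 had a log10 peak number of 4.42, apart from the other p53 knockout libraries (gap to the nearest library over the range of all 4, 0.831). Among the 8 ESC libraries with wild-type WDR5, parental replicate 2 stood apart in log10 peak number (3.73), gene end share (44.2%) and share in clustered windows (21.9%), with gaps over the range of 0.838, 0.597 and 0.819. On chromosomes 1 to 19, X and Y, median peak width was 36.75 bp larger in backbone double knockout than in parental ESCs, and in embryoid bodies the difference was -13 bp; the difference between these effects was not tested. Sequences outside chromosomes 1 to 19, X and Y, not used in the report, held 1.39% and 2.29% of peaks in backbone ESCs and at most 0.634% in parental ESCs. In number these were 35 and 36 peaks against 34 and 47, with 33 to 47 in all 12 ESC lists, so the larger share comes from the short backbone lists.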

How the results depend on the processing

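Clustered windows, chromosome 8, gene span assignment and the 6 wide-peak lists were chosen as alternatives only after the data were seen. Clustered windows come from backbone replicate 1, so a fall in backbone-only regions on their removal is favoured by construction. Depth is unknown and the lists are of unequal length; the first-named group's count comes first below, and causes were not tested unless stated. Counts of regions found only in 1 group stayed within 1.5 times with peaks up to 200 bp apart merged, 500 bp summit windows (ESC only, since embryoid body lists have no summits), overlap of 50% of the shorter peak, and autosomes only. Gene end shares were recomputed with windows of 500 and 2500 bp, and none of their differences moved or reversed; other results were not recomputed under these settings. The motif comparisons planned with GC-matched regions and another window were not run, for want of a genome sequence.

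Equal list length moved 14 results, reversed 3 and left 25, where a gene end difference counts as left if it kept its sign. Among those left, the gene end difference of backbone against p53 knockout went from -4.40 to -47.0 points. That of WDR5WT against backbone went from 7.25 to 52.7 points. P53 knockout against parental gave 918 p53-knockout-only regions, 2 lists past adjustment and a gene end difference of 14.8 points (reversed). Backbone gave 674 p53-knockout-only regions against p53 knockout, 334 and 332 against parental, and 823 WDR5WT-only against WDR5WT. S91K-Y191F gave 274 and 261 against backbone, and against WDR5WT 1318 WDR5WT-only regions, 3 lists and a gene end difference of -16.9 (reversed). Embryoid bodies against parental ESCs gave 2509 regions, 0 lists and a gene end difference of 0.638 (reversed). The 4-against-8 sets fell to 10 and 32 regions. By construction, shorter lists hold fewer regions, and lists of equal length bring the counts of the compared groups close together.

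With the upper 50% of each list by the authors' p, which removes peaks by construction, 19 counts fell by over 1.5 times: p53 knockout against parental 2991 and 588, H9-only 1095, backbone against p53 knockout 483 and 9114, against parental 62 and 1490, WDR5WT against backbone 12145 and 483, S91K-Y191F against backbone 1323 and 45, against WDR5WT 496 and 6702, WDR5WT against p53 knockout 697 and 459, double knockout against parental embryoid bodies 3950 and 3861, and embryoid bodies against ESCs 25721 and 822. The 4-against-8 gene end difference became -6.73 (reversed; exact permutation p = 0.347).

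Without clustered windows, parental-only regions against p53 knockout numbered 632, backbone-only regions 184 against p53 knockout, 13 against parental, 187 against WDR5WT and 15 against S91K-Y191F, mutant-only regions against WDR5WT 370, ESC-only regions against embryoid bodies 996 and regions in all 4 without wild-type WDR5 3. Gene end differences of backbone reversed to 12.2 against p53 knockout and 0.335 against parental, and that of WDR5WT against backbone to -9.34. Embryoid bodies against ESCs then had 5 lists past adjustment. The 4-against-8 gene end difference became 11.6 (exact permutation p = 0.0263), and that of top peaks -20.1 (p = 0.0505). Within the 6 wide-peak lists the 4-against-8 differences were -0.430, -3.34 (reversed) and -6.47, where 4 against 2 libraries cannot pass the threshold.

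Without chromosome 8, backbone-only regions against parental numbered 57. Requiring 3 of 4 p53 knockout libraries gave 9441 p53-knockout-only regions against parental and 2167 against WDR5WT. Allowing 1 exception per side gave 272 and 9936 regions in the 4-against-8 sets. Assignment within 50 kb and by gene span each gave 4 lists for embryoid bodies against ESCs.

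Leaving out each library in turn loosens the requirement, so region counts rise by construction: p53 knockout against parental 5631 to 16220 and 1162 to 5483; C9 against H9 1913 to 4684 and 3008 to 4831; backbone against parental 137 to 300 and 2929 to 22190; S91K-Y191F against backbone 2658 to 13941 and 108 to 180, against WDR5WT 989 to 3099 and 13603 to 21917; WDR5WT against p53 knockout 1678 to 4321 and 1064 to 1637; double knockout against parental embryoid bodies 9324 to 29113 and 8474 to 26031, with 0 to 3 lists; embryoid bodies against ESCs 42531 to 74969 and 1681 to 8171. The 4-against-8 differences ran from -0.944 to -0.602 in log10 peak number (called throughout), from -2.34 to 7.62 in gene end share and from -34.4 to -20.9 among top peaks.

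With replicate number as a replicate block, the 4-against-8 differences of -0.749 in log10 peak number, 1.55 in gene end share and -28.1 among top peaks had p = 0.00889, 0.778 and 0.0178 (exact permutation within replicate number). Replicate numbers do not pair libraries of different groups: over 15 pairs of ESC groups the check gave r of -0.343 to 0.104, and 0.00245 in embryoid bodies. Mean similarity within groups stayed above that between groups with the lists as deposited and with the top 500 peaks.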

Other observations

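The counts over splits of 12 libraries in this part were chosen only after the result was seen.

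Gene ends of single lists add to the picture of embryoid bodies. Hox genes, positional regulators of the trunk, had an end peak at 25 and 24 of 39 members in parental embryoid bodies and at 14 and 25 in double knockout embryoid bodies, so the low value rests on double knockout replicate 1. P53 targets had one at 29 of 30 members in each embryoid body library, with or without p53, COMPASS and MLL subunits at 16 or 17 of 18, ribosomal protein genes at 78 or 79 of 84, and neuroectoderm genes at 24 or 25 of 25; over all genes the share was 64.6% to 66.7%.

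In ESCs, p53 targets had an end peak at 22 and 10 members in parental, 20 and 23 in C9, 24 and 24 in H9, 24 and 27 in WDR5WT, 9 and 16 in S91K-Y191F and 0 and 4 in backbone lists. Neuroectoderm genes had one at 12 and 1 members in parental, 14 and 17 in C9, 18 and 20 in H9, 23 and 24 in WDR5WT, 1 and 7 in S91K-Y191F and 0 in both backbone lists. Primitive streak and mesoderm genes had one at 5 and 0 members in parental, 10 and 11 in C9, 9 and 10 in H9, 14 and 13 in WDR5WT, 0 and 3 in S91K-Y191F and 0 in both backbone lists. Over all genes the shares were 40.8% and 12.4% in parental, 43.0% and 44.3% in C9, 48.2% and 48.8% in H9, 49.4% and 54.9% in WDR5WT, 13.1% and 33.8% in S91K-Y191F and 1.24% and 4.90% in backbone lists. The values of the lists were not tested against these shares.

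For the 58 regions found in all 8 libraries with wild-type WDR5 and none of 4 without, such as that at Dicer1, 1 of 100 splits of the 12 libraries, the real one, gave as many, and the highest other split gave 3. The count at equal list length was 32, again with 1 of 100 splits as large and 3 in the highest other. Most of these splits part replicates of a group, which are alike. Of the 15 splits that keep replicates together, the real one gave the most. The highest other split set backbone and parental lists against the rest, with 46 for the lists as deposited and 12 at equal list length. Parental ESCs have wild-type WDR5, so with the lists as deposited a similar count arose from a grouping that does not follow WDR5. The 15 splits are too few for a share under 0.05.

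For the total in both directions, 83, chance is not excluded with the lists as deposited, since 6 of 100 splits gave as large a total, and 5 of the 15 that keep replicates together. The total at equal list length was 42, with 1 of 100 splits as large and 10 in the highest other, and 36 in the highest other of the 15, again too few for a share under 0.05. With the lists as deposited, the highest other of the 100 splits, with 240 regions, set C9 replicate 2, H9 replicate 2 and both WDR5WT libraries against the rest, and the highest other of the 15, with 614, set C9 and H9 against the rest. Splits with several times the real total point to a structure of the samples. The libraries of the former are 4 of the 5 longest ESC lists, so list length may be part of it.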
